A study of Mus musculus with 2 samples.

How the data were processed

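H3K27ac ChIP-seq peak lists of newborn mouse kidney were analysed, from 2 libraries labelled as biological replicates of a single group (mouse strain B6NTac;B6NCrl/Lap, males and females pooled). The labels give 15 pooled mice for replicate 1 and no number for replicate 2, so separate litters or pools of that size cannot be assumed.

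Per the README files deposited with the samples, the lists are narrowPeak intervals on the assembly mm10, derived from the alignments of each replicate together with further files taken here to be the control. One list was called on each replicate alone, another on both replicates pooled, and the last is named replicated peaks. The aligner, peak caller, their versions and the threshold are not given in the sources used here, nor is the rule that makes a peak replicated. The score of a peak in the deposited lists is a whole number whose scale is not given in the sources used here, and the authors' score was used only to rank peaks within a list. The enrichment in the deposited lists is a ratio, taken from the definition of the narrowPeak format to be the fold over control at the peak. The authors' q-values are deposited as -log10 of q, again by the definition of the format. The offset of the summit from the start of each interval, as deposited by the authors, gave the summit position. The replicated list was not strict on q: 98.3% of its peaks had q of at most 0.01 and 0.297% had q above 0.05. In the lists of replicates 1 and 2, 11.3% and 6.40% of peaks had q above 0.05. No reads or counts were used, so depth is unknown and no interval here covers sequencing depth.

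Coordinates were read against GRCm38, the sequence of mm10, with GENCODE release M21 genes. All peak ends were checked to lie within the chromosome lengths. Coordinates are printed 1-based. Peaks on unplaced scaffolds (7 of the replicated list) were left out. A promoter was 1000 bp either side of any annotated start site of the 21938 protein-coding genes (93513 distinct start sites). Peaks were classed in the order promoter, other exon, intron, intergenic, and random placements kept chromosome and length over bases that are not N. For acetylated length, each replicated peak went to the gene with the nearest start site within 100000 bp of its midpoint. This left 48950 of the peaks assigned (93.2%). A wide peak counts for a single gene, so Hoxb5 has no assigned length although the peak of Hoxb4 covers its promoter. The values were log2(1 + bp), set against 10000 random lists drawn without replacement and matched on 10 classes of the width of the nearest-gene territory, a permutation test of list membership. The smallest p that 10000 lists allow is 0.0002 and that of 1000 placements 0.002. Promoter shares of lists were tested with two-sided Fisher exact tests, and all families were adjusted by Benjamini-Hochberg over 28 lists, 23 motifs or 4 classes. The class comparisons used Fisher exact tests and permutation tests with 100000 resamples, adjusted over 4 tests together, with Newcombe intervals for shares and 10000 bootstrap draws for means. Domains were made by joining replicated peaks up to 12500 bp apart and ranked by summed peak length. A domain was given the gene with the start site nearest its midpoint. The domain test departed from the fixed plan: its background of 13126 genes held, besides the 13121 with an assigned peak, 5 genes nearest to a top domain that had none. Motifs were searched on both strands as exact matches to a consensus within 250 bp of the summits of distal peaks. Control windows lay 5000 bp to either side outside all pooled peaks. Peak and control windows were drawn to equal numbers in each 2% GC bin, which left 32696 of 36779 peak windows at a mean GC of 48.1%.

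The 28 gene lists, the motifs, the tests, the rule for named genes and the alternatives, except those named as later additions, were fixed before the data were examined. Of 654 listed symbols 653 matched a protein-coding gene, and 31 genes are in more than 1 list. The lists are markers of nephron progenitors, renal vesicle, ureteric bud and collecting duct, podocyte, proximal tubule, loop of Henle, distal convoluted and connecting tubule, intercalated cell, stroma, endothelium, macrophage, erythroid, adrenal, gonad, hepatocyte, muscle, neuron, lung, gut and pancreas, and pluripotency. They also cover Hox genes in 3 groups, renal endocrine genes, signalling, cell cycle, oxidative phosphorylation and immediate early genes. Named genes are the 25 with the most assigned bp; up to 4 members of each list with the most bp and up to 3 without a promoter peak; those nearest the 15 longest domains and the 10 peaks of highest enrichment; and Hox genes. Fos, Star, Junb, Six1 and Cubn lie outside the rule and were chosen after their values were seen.

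Alternatives were: peaks with q of at most 0.01; the list of each replicate alone; the pooled list; promoter windows of 500 and 2500 bp; the most 5′ start site only; lists matched on 10 classes of promoter GC; a reach of 25000 bp; numbers of peaks; stitching at 5000 bp; 250 domains; motif windows of 100 bp; and controls 20000 bp away. After the data were seen, genes of 1 list only, replicated peaks that touch both replicates, random lists with no matching, and the domain background as planned were added. The random lists separate the form of the test from the matching on GC. The GC content of a promoter was that of 1000 bp either side of the most 5′ start site alone. A promoter peak could lie at any start site. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

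The steps were tested on simulated data. No class was called in 80 tests of random placements. Of 10 planted lists of 20 genes, 5 were called at a promoter rate of 0.85 and 10 at a rate of 0.15, and no unchanged list was. For acetylated length, 6 of 10 lists raised by 3 on the log2 scale were called. The motif step called only the planted AP-1 of 23 motifs. That check used 1191 windows of random sequence with equal base frequencies, and AP-1 was planted at 20% of summits. Real sequence is not uniform and the differences in share found in it were smaller. The check therefore gives no rate of false or missed calls for the real motifs. A difference of 1 SD between groups of 30 genes was called in 19 of 20 draws, and 10 of 200 unchanged draws were called. The number of unchanged draws was raised to 200 after a first, smaller set had given a higher share of calls. Lists of this size can therefore miss a rise in promoter share as large as from 55.1%, the share of all genes, to a rate of 0.85.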

Results

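H3K27ac, the acetylation of lysine 27 on histone H3, marks active promoters and enhancers. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in kidneys of newborn mice (postnatal day 0). The series held 1 group of 2 libraries, which the labels call biological replicates. Replicate 1 came from kidneys of 15 pooled mice. Replicate 2 came from a pool whose size the labels do not give. Both pools mixed males and females. The files held 4 lists of peaks, the intervals where the signal stood above the control. There was a list for each replicate, a list called on both replicates pooled, and a list of replicated peaks, which is the main list below. The labels name no second condition, so the comparisons are between replicates, gene groups and regions within this tissue. The files used held no read counts, so the depth of the libraries is unknown. Every p-value treats genes, peaks or windows as its units and describes these lists, not differences between animals. The labels name kidney tissue and no sorted cells. A missing peak therefore does not show that the mark is absent from a less frequent cell type.

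The replicated list held 52510 peaks on chromosomes 1 to 19, X and Y. They covered 47050241 bp, or 1.78% of the sequenced bases. Their median length was 627 bp, from 185 bp to 27893 bp. Replicate 1 alone gave 80956 peaks over 1.53% of the genome, and replicate 2 gave 86666 peaks over 1.84%. At least 1 bp of 67.9% of the replicate 1 peaks lay in a replicate 2 peak (95% Wilson interval 67.6% to 68.2%). Randomly placed intervals gave 3.51% ± 0.0686 (SD over 100 placements). In the other direction the share was 57.9% (57.6% to 58.2%), against 3.21% ± 0.0573 for random places. Sharing followed the authors' score. Each list was split by score into 10 equal parts. In replicate 1, 8095 of the 8096 peaks of the highest part were shared and 39.8% of those of the lowest. In replicate 2 the share was 100% in the highest part and 25.3% in the lowest. Median peak length also fell from the highest to the lowest part, from 1270.5 to 213 bp in replicate 1 and from 1466 to 222 bp in replicate 2. A longer peak is more easily touched by 1 bp, and the random shares are over all peaks. Score and length were therefore not told apart. When at least 50% of a peak had to be covered, the overall shares were 59.2% and 45.9%. Across 33476 peaks that matched singly in both replicate lists, enrichment had a Spearman correlation of 0.69. That value is across peaks, which are not independent replicates. Of the replicated peaks, 44493 (84.7%) touched peaks of both replicates, 2247 touched replicate 1 alone, 5570 touched replicate 2 alone and 200 touched neither.

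**Figure D1:**
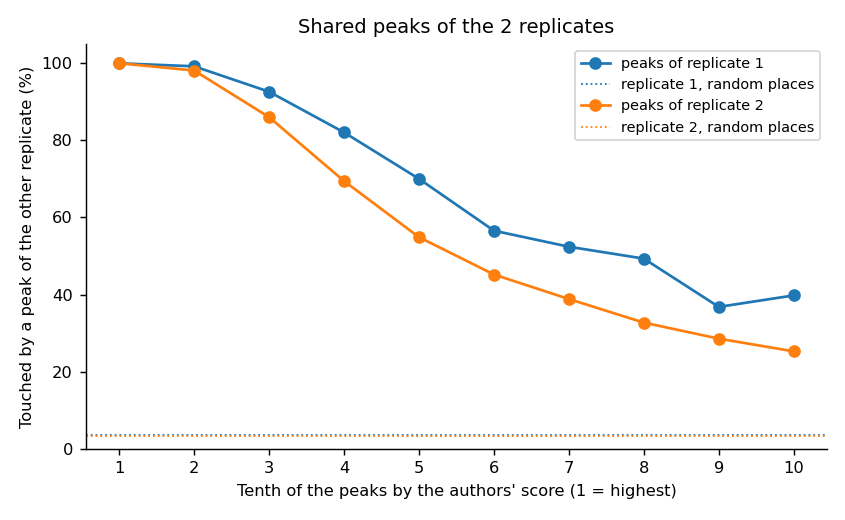
Percentage of the peaks of each replicate touched by at least 1 bp of a peak of the other replicate (vertical axis), in 10 equal parts of the list ranked by the authors' score (horizontal axis, 1 is the highest). Solid lines are the 2 replicates and dotted lines their shares at random places over all peaks, 3.51% and 3.21%. Sharing is near complete in the highest part and low in the weakest parts.

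The strongest peaks lay at promoters, among them those of Ep300 and Brd2. By bp of peaks summed over the nearest gene, the longest acetylation lay around Rbpms, Zmiz1 and Tns1. The enrichment of a peak is the authors' own value. The 10 replicated peaks with the highest enrichment, from 47.4-fold to 53.8-fold, all had their midpoints at promoters. They belonged to Epc1, Brd2, Kmt5b, Arid2, Klf7, Ep300, Pnrc1, Kansl1, Nr2c2 and Fem1c. Ep300 encodes an acetyltransferase that deposits H3K27ac, and Brd2 a protein that binds acetylated histones. The Epc1 peak lay at mm10 chromosome 18, 6490023 to 6491681. By total length of assigned peaks, Rbpms, an RNA-binding protein gene, led all protein-coding genes with 74341 bp in 68 peaks. It had 60660 bp in replicate 1 and 71694 bp in replicate 2. Zmiz1, a transcriptional coregulator gene, had 72627 bp (56206 and 69475 bp in the replicates). Tns1, which encodes the focal adhesion protein tensin 1, had 70946 bp (53757 and 73340 bp). Further down the 25 leading genes stood Col4a1, a collagen of basement membranes, with 43487 bp. Smad7, an inhibitor of TGF-beta signalling, had 42309 bp. Ezr, which encodes the membrane linker ezrin, had 40592 bp, and Myh9, a non-muscle myosin gene, 40036 bp. All 25 had a replicated peak at the promoter and a peak there in each replicate.

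By their midpoints, 15726 of the 52510 replicated peaks (29.9%) lay within 1000 bp of an annotated start site of a protein-coding gene. Random placements on the same chromosomes gave 4.09% ± 0.0881 (SD, 1000 placements), so promoters held 7.33 times the random share. Intergenic sequence held 22.4% against 50.6% ± 0.224. Introns held the largest share of peaks, 42.7%, which was close to the random 41.3% ± 0.216. Exons held 4.96% against 4.03% ± 0.0869. Each of these 4 shares differed from random placement (permutation of peak positions, adjusted p = 0.002, the smallest possible). The excess in introns turned to a deficit, 0.980 times random, when promoters were taken as 2500 bp either side. Counted by any overlap, the exon share was 0.969 times random (permutation of positions, adjusted p = 0.0180), but 1.07 and 1.11 times in the lists of replicates 1 and 2.

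In total 12087 of 21938 protein-coding genes (55.1%) had a replicated peak within 1000 bp of a start site. The share was higher than among other genes for podocyte, renal vesicle, ureteric bud, loop of Henle, distal convoluted tubule, stroma and endothelium lists. Not all of these calls held under other settings, as given below. Of 25 podocyte genes, 23 (92.0%) carried a promoter peak. They included Actn4, an actin crosslinker of podocyte foot processes, with a promoter peak of 13.9-fold and 39148 bp of assigned peaks, and Bmp7, a growth factor gene, with 16.0-fold and 21587 bp. Synpo, which encodes synaptopodin, had 6.35-fold and 18552 bp. The exceptions were Nphs1, which encodes the slit diaphragm protein nephrin, and Trpc6, a cation channel gene. Of 20 genes of the renal vesicle and early nephron, 17 (85%) had promoter peaks. Pax8, a transcription factor of early nephrons, led them with 22 peaks and 29528 bp (23382 and 31367 bp in the replicates). Notch2, a receptor needed for proximal nephron fate, had 26974 bp, and Hnf1b, a regulator of tubule genes, 23915 bp. Bmp2 and Fgf8 had no replicated promoter peak.

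The ureteric bud and collecting duct list had 21 of 28 members (75%) with a promoter peak. Its longest acetylation was at Hoxb7, a marker of the ureteric bud, in a single peak of 19065 bp and 34.3-fold that also covers the promoters of Hoxb6 and Hoxb8. Wnt7b, a signal for medulla formation, had 19 peaks and 18516 bp, and Grhl2, an epithelial transcription factor gene, 15648 bp. Ret, the receptor for Gdnf at ureteric tips, and the water channel gene Aqp4 had none. In the loop of Henle list 18 of 23 genes (78.3%) had a promoter peak, among them Kcnj1, a potassium channel gene, and Cldn19, a tight junction gene. In the list of the distal convoluted and connecting tubule it was 16 of 20 (80%), among them Fxyd2, a subunit of the sodium pump, and Stk39, a kinase of the sodium chloride cotransporter pathway. The loop of Henle call was lost in replicate 2 alone (Fisher adjusted p = 0.0731) and the distal tubule call in replicate 1 alone (adjusted p = 0.138). Renal stroma and mesangium had 27 of 31 (87.1%). Meis2 (37867 bp) and Meis1 (16771 bp), homeobox genes of stroma, and Col1a1 (15892 bp), a fibrillar collagen gene, led that list. Ren1, which encodes renin, Postn and Tbx18 had no promoter peak. Endothelium had 28 of 31 (90.3%), led by Notch1 (30879 bp), the transcription factor gene Ets1 (23628 bp) and Egfl7 (20941 bp).

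In 3 further lists of kidney cell types the share did not pass the test, which leaves a difference open. Nephron progenitors had 16 of 22 (72.7%, Fisher exact test, adjusted p = 0.161). Pax2, needed for kidney formation, had 26691 bp (24544 and 29055 bp in the replicates), and Sall1, another regulator of progenitors, had a promoter peak of 24.4-fold. Cited1, Meox2 and Osr1 had no replicated promoter peak. Proximal tubule genes had 23 of 36 (63.9%, Fisher adjusted p = 0.343). Peaks lay at the promoters of Pck1, an enzyme of gluconeogenesis, of the regulators Hnf1a and Hnf4a, and of Slc3a1, part of a cystine transporter, while Acsm2, Cyp2e1 and Kap had neither a promoter peak nor any assigned peak. Intercalated cell genes had 8 of 18 (44.4%, Fisher adjusted p = 0.478), with 15482 bp at Tfcp2l1 and 15141 bp at Atp6v0a4, a proton pump subunit. In the lists of single replicates the progenitor share passed the threshold (Fisher exact test, adjusted p = 0.0112 in replicate 2 and 0.0219 in replicate 1). Against lists matched on promoter GC content the progenitor difference was 2.71 percentage points (permutation adjusted p = 0.991), down from 17.6.

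Among lists that any tissue could share, 27 of 28 genes of oxidative phosphorylation (96.4%), 25 of 28 of the cell cycle (89.3%) and 23 of 25 immediate early genes (92.0%) had promoter peaks. The immediate early genes include Jun, Fos and Ier5, which respond within minutes to stress or growth factors. Junb carried a single peak of 7232 bp. Signalling genes of kidney development had 27 of 34 (79.4%), with 21808 bp at the receptor gene Fgfr2. Renal endocrine genes had 14 of 21 (66.7%, Fisher adjusted p = 0.395). Promoter peaks lay at Vdr, the vitamin D receptor gene, and of Kl, which encodes klotho, while Agtr1b and Ren1 had none.

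Genes of most other organs rarely had a promoter peak. A promoter peak was present at 0 of 20 genes of pluripotency and the germ line, 2 of 27 neuronal genes (7.41%) and 3 of 26 genes of heart and skeletal muscle (11.5%). The counts were 4 of 25 for gut and pancreas (16.0%), 3 of 18 for gonad (16.7%) and 5 of 26 for hepatocytes (19.2%). The muscle genes with one included Tnni1 (4575 bp), a troponin of slow muscle, and those without included Actc1 and Acta1, cardiac and skeletal actins. The hepatocyte gene with the longest acetylation was Apoh, with 5332 bp, and the albumin gene Alb had none. Macrophage and leukocyte genes had 4 of 24 (16.7%), with 3 of 24 in replicate 1 and 7 of 24 (29.2%) in replicate 2, and stayed below other genes in both. Erythroid genes had 7 of 18 (38.9%, Fisher adjusted p = 0.263), among them Tmcc2 and Tspan33 but not Alas2, the enzyme of haem synthesis in red cells. The adrenal gland, which lies on the kidney, had 4 of 20 (20.0%): Scarb1, Fdx1, Slc18a1 and Star. Star was the only 1 of 7 core steroidogenic genes with a promoter peak. Lung epithelium had 8 of 20 (40%, Fisher adjusted p = 0.216), including Etv5 and Hopx. Etv5 also belongs to the ureteric bud list.

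Over the 28 lists, 13 lay above the other genes and 8 below by two-sided Fisher exact tests with Benjamini-Hochberg adjustment. Adjusted p-values of the lists above ran from 2.36e-05 (oxidative phosphorylation) to 0.0491 (ureteric bud and collecting duct). Those below ran from 3.08e-06 (pluripotency and germ line) to 0.00454 (adrenal). Random lists in place of the Fisher test, with no matching, left 10 lists above. Ureteric bud (permutation adjusted p = 0.0653), loop of Henle (0.0530) and distal convoluted tubule (0.0546) missed the threshold with differences of 19.8, 23.0 and 24.8 percentage points. Random lists matched on promoter GC content left 4 above: stroma, endothelium, cell cycle and oxidative phosphorylation. Matching took the difference from 37.1 to 16.8 points for podocyte (permutation adjusted p = 0.114), from 29.9 to 8.83 for renal vesicle (0.567), from 24.4 to 7.90 for signalling (0.437) and from 36.8 to 16.0 for immediate early genes (0.119). It stayed at 20.96 points for loop of Henle (permutation adjusted p = 0.0528) and was 19.2 for distal convoluted tubule (0.114) and 8.27 for ureteric bud (0.496). The 8 lists below stayed below in both, but in the pooled list the adrenal difference (-24.2 points) missed the threshold.

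**Figure D2:**
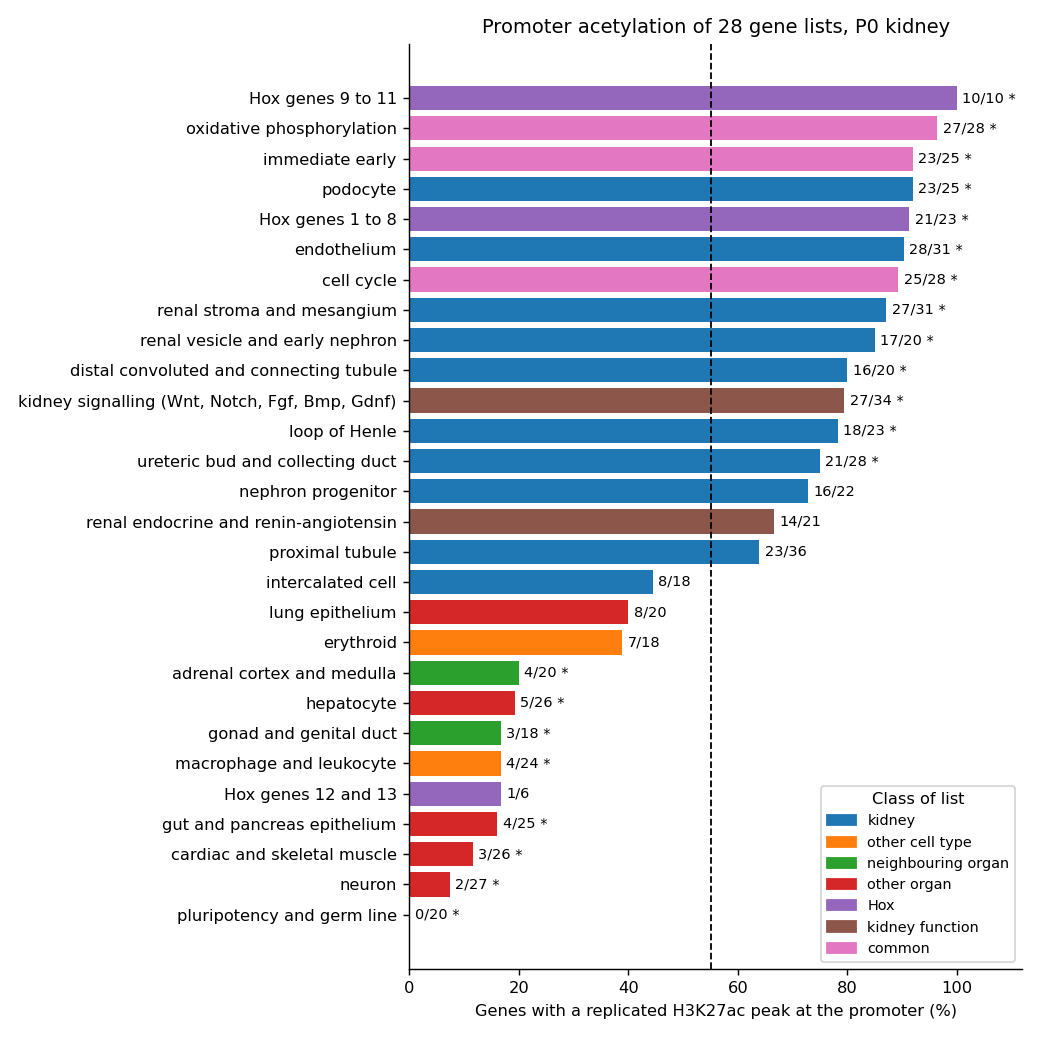
Percentage of the genes of each of 28 lists with a replicated H3K27ac peak within 1000 bp of a start site (horizontal axis), coloured by the class of the list. Labels give genes with a peak over genes in the list, asterisks an adjusted Fisher p under 0.05, and the dashed line the 55.1% of all protein-coding genes; kidney lists lie mostly to its right and lists of other organs to its left.

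Hox genes, which set position along the body, carried promoter peaks in groups 1 to 11 and rarely in groups 12 and 13. Of the genes of groups 1 to 8, 21 of 23 (91.3%, Fisher exact test, adjusted p = 0.000527) had a promoter peak; Hoxb1 and Hoxd1 did not. All 10 genes of groups 9 to 11 had one (Fisher adjusted p = 0.00509). Of the 6 genes of groups 12 and 13, only Hoxd12 did, with 3.71-fold (Fisher adjusted p = 0.123). Hoxd11 and Hoxa11, regulators of nephron progenitors, had promoter peaks of 17.2-fold and 10.6-fold. The longest replicated peak of all, 27893 bp, covered Hoxb4 and its promoter (chromosome 11, 96303376 to 96331268). Against GC-matched lists groups 1 to 8 lay 21.2 percentage points above (permutation adjusted p = 0.0541) and groups 9 to 11 lay 26.7 points above (adjusted p = 0.119), both short of the threshold. Groups 12 and 13 lay below (-61.0 points, permutation adjusted p = 0.0122). Hox genes lie in clusters and neighbours can share a peak, as Hoxb6, Hoxb7 and Hoxb8 do. The tests of Hox groups, here and below, therefore count genes that are not independent units.

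**Figure D3:**
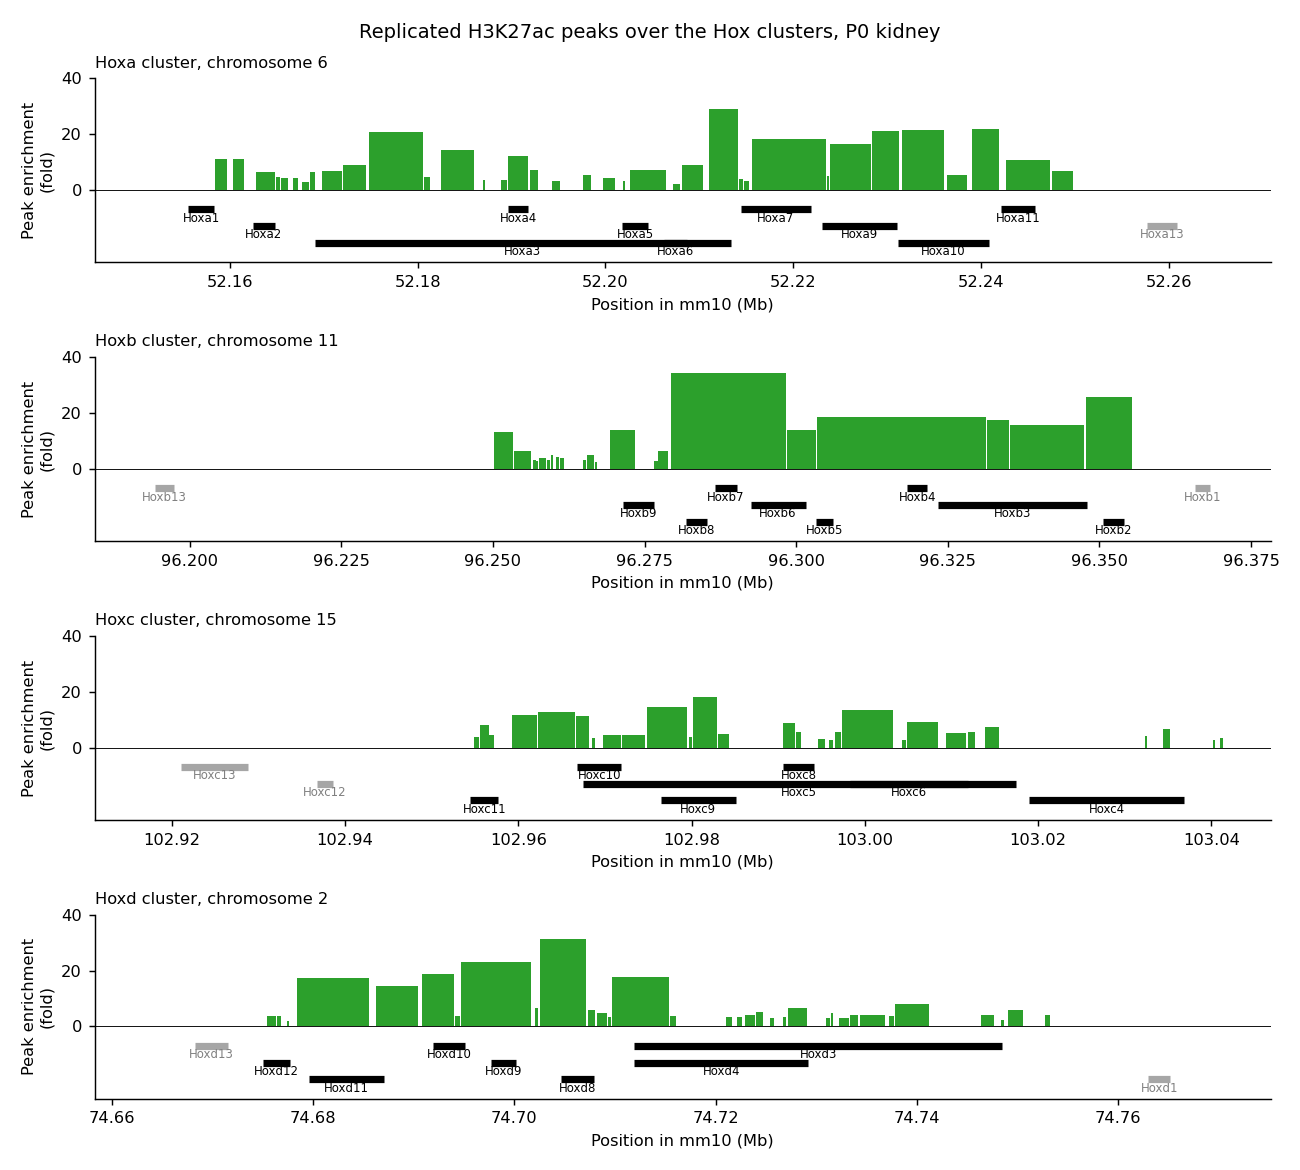
Replicated peaks (green) over the 4 Hox clusters, with position in mm10 in Mb on the horizontal axis and the authors' peak enrichment on the vertical axis. Bars below are genes, black with a replicated promoter peak and grey without; grey genes are Hoxb1, Hoxd1 and those of groups 12 and 13 except Hoxd12.

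The acetylated length assigned to a gene, its promoter peak included, was above random for several kidney lists. It is not independent of the promoter share, since the median gene with a promoter peak had 1911 bp and the median gene without one 0 bp, so it does not show a wider spread. The mean of log2(1 + bp of assigned peaks) was compared with random lists matched on the width of each gene's surroundings, a permutation test of list membership. These random lists were not matched on promoter GC content. With that matching the promoter shares of podocyte, renal vesicle, ureteric bud and signalling genes had missed the threshold. Podocyte genes were 4.17 above random (permutation adjusted p = 0.0007, the smallest reached). Endothelium was 4.36 above, the ureteric bud and collecting duct 3.82, stroma 3.68 and signalling genes 3.76 (permutation adjusted p = 0.0007 for each). Renal vesicle genes were 3.83 above (permutation adjusted p = 0.0028), distal convoluted tubule 3.11 (adjusted p = 0.0146) and proximal tubule 2.28 (adjusted p = 0.0189). In replicate 1 alone the distal tubule lay 2.33 above (permutation adjusted p = 0.0551). Immediate early genes were 5.09 above, Hox groups 9 to 11 were 7.52 above and Hox groups 1 to 8 were 6.08 above (permutation adjusted p = 0.0007). Oxidative phosphorylation was 2.95 above (permutation adjusted p = 0.00689) and the cell cycle 2.43 (adjusted p = 0.0194). For both of these the difference was no longer past the threshold when peaks were counted in place of their length. Nephron progenitors (2.23, permutation adjusted p = 0.0611) and loop of Henle (2.18, adjusted p = 0.0603) missed the threshold, although both passed it in each single replicate (progenitors 3.37 and 2.54, loop of Henle 3.06 and 2.36). Intercalated cells (0.57, permutation adjusted p = 0.691), renal endocrine genes (1.45, adjusted p = 0.264) and lung epithelium (0.35, adjusted p = 0.782) did too. Lists below random were pluripotency and germ line (-4.95, permutation adjusted p = 0.00124), gut and pancreas (-3.92, adjusted p = 0.00168), neuron (-3.67, adjusted p = 0.0028), muscle (-2.90, adjusted p = 0.0144) and hepatocyte (-2.61, adjusted p = 0.0205). The hepatocyte call was lost when peaks were counted and in replicate 1 alone (-1.97). Gonad (-2.74, permutation adjusted p = 0.0510), adrenal (-2.29, adjusted p = 0.0806), Hox groups 12 and 13 (-4.44, adjusted p = 0.0603), erythroid (-1.37, adjusted p = 0.324) and macrophage genes (-0.89, adjusted p = 0.438) were not called.

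Taken as a class, kidney genes and genes of other organs stood far apart. The other-organ class held, besides organ lists, the pluripotency and germ line genes (0 of 20 with a promoter peak), which stand for no single organ. The kidney class held endothelium (28 of 31) and stroma (27 of 31), cell types not confined to kidney. The contrast is therefore not purely between organs. Of 243 genes in the 10 lists of the kidney class, 188 (77.4%) had a promoter peak. Of 142 genes in the 6 lists of the other-organ class, 21 (14.8%) had one. The difference was 62.6 percentage points (95% interval 53.8 to 69.5), with an odds ratio of 19.7 (two-sided Fisher exact test, adjusted p = 7.48e-34). The median gene of the kidney class had 3308 bp of assigned peaks and that of the other class 0 bp. On the log2 scale the means were 10.22 ± 4.37 (SD over genes) and 3.63 ± 5.14. Their difference of 6.59 (95% bootstrap interval 5.57 to 7.58) had a permutation p of 1e-05, the smallest possible with 100000 resamples.

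Within the kidney, genes of progenitors and of the differentiated proximal tubule could not be separated. Nephrons still form in the newborn mouse kidney, so both cell states are present. Promoter peaks were found at 72.7% of 22 progenitor genes and 63.9% of 36 proximal tubule genes. The difference was 8.84 percentage points (95% interval -16.1 to 30.4; Fisher exact test, adjusted p = 0.757). The mean log2 lengths, 9.58 ± 5.47 and 9.16 ± 4.76 (SD over genes), differed by 0.42 (95% bootstrap interval -2.28 to 3.05; permutation test, adjusted p = 0.757). In single replicates the differences were 17.9 and 14.1 percentage points and 1.07 and 1.24 on the log2 scale (replicates 1 and 2), again short of the threshold. The intervals leave room for a sizeable difference in either direction.

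The stitched domains with the most acetylated sequence included the Hoxb, Hoxa and Hoxd clusters. Joining neighbouring replicated peaks gave 19728 domains. The 500 with the most acetylated sequence held 15.3% of the peaks and 20.5% of the acetylated bp. Their median acetylated length was 16365 bp, against 1329 bp for all domains. The domain with the most acetylated sequence covered most of the Hoxb cluster (mm10 chromosome 11, 96250210 to 96355347), with 93336 bp in 21 peaks, or 88.8% of its span. The Hoxa domain (chromosome 6, 52158398 to 52249857) ranked 3 with 71843 bp, and the Hoxd domain, nearest Hoxd4, ranked 7 with 54331 bp. Rank 2 went to a domain of 85010 bp on chromosome 2 (30586976 to 30835147), whose midpoint lay 85602 bp from the nearest start site, that of 1700001O22Rik. Rbpms, Col4a1, Myh9, Irf2bpl, Trim8, Zmiz1, Ahdc1, Thra, Ski, Tns1 and Frmd8 were nearest to the other 11 of the leading 15.

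Genes of 3 lists were nearest to a top domain more often than other genes with assigned peaks or nearest to a top domain, of which 3.67% were. They were renal vesicle (4 of 19, Pax8, Pou3f3, Hnf1b and Notch2), endothelium (5 of 29, among them Notch1, Fli1 and Egfl7) and signalling (5 of 31, among them Notch1, Notch2 and Bmp7). Each had an adjusted Fisher exact p of 0.0483. Podocyte (4 of 23), Hox groups 1 to 8 (4 of 22) and immediate early genes (4 of 24) came to 0.0507. The fixed plan had named only the 13121 genes with an assigned peak, and the 5 others had been let in. With the planned background the same 3 lists were above (Fisher exact test, adjusted p = 0.0463 for each). Podocyte and immediate early genes then came to 0.0588, and Hox groups 1 to 8, without Hoxb5, to 3 of 21 (Fisher adjusted p = 0.159). None of the 29 proximal tubule genes with assigned peaks was nearest to a top domain, though 2 of 29 were at a stitching distance of 5000 bp (Fisher adjusted p = 0.686). At a stitching distance of 5000 bp renal vesicle (3 of 19, Fisher adjusted p = 0.109) and endothelium (2 of 29, adjusted p = 0.686) lost the call, and progenitor, podocyte, stroma, Hox 1 to 8 and immediate early genes gained it beside signalling. When peaks had to touch both replicates, signalling was the only list above. Unlike the test of acetylated length, the domain test was not matched on the width of a gene's surroundings. The lists also overlap: Notch1 counts for endothelium and signalling, and Notch2 for renal vesicle and signalling.

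Several sequence motifs, among them those of HNF1, FOX, TEAD, SOX and MEF2 factors, were more frequent near distal summits than in flanking sequence. Distal peaks had midpoints over 1000 bp from any start site of a protein-coding gene. Peaks at promoters of genes that do not encode proteins could therefore be among them. In 32696 summit windows and as many control windows of the same GC content, 14 of 23 motifs were enriched and none depleted (Fisher exact tests, Benjamini-Hochberg adjustment). The HNF1 motif GTTAATNATTAA, bound by regulators of tubule genes, was in 38 peak windows and 4 controls (Fisher exact test, adjusted p = 2.15e-07). The ratio of 9.50 rests on few controls and was 4.00 in replicate 2 alone and 3.59 in replicate 1 alone. The HNF4 motif CAAAGTCCA, of a nuclear receptor of the proximal tubule, was 1.36 times as frequent (Fisher adjusted p = 0.00100), and 1.18 times with controls 20000 bp away (Fisher adjusted p = 0.0753). The GRHL motif was 1.93 times as frequent, but 1.16 times in replicate 2 alone (Fisher adjusted p = 0.377) and 1.40 times with controls 20000 bp away (adjusted p = 0.0962). The motif TCAGGTTTC, the site of Six2 and its relatives, was 1.52 times, TEAD 1.53 times, ETS 1.53 times, MEF2 2.43 times and FOX 1.43 times as frequent. The E-box CAGCTG, bound by TCF21 and other bHLH factors, was in 31.2% of peak windows and 25.9% of controls (Fisher adjusted p = 1.31e-49). SOX (1.28), TFAP2 (1.24), AP-1 (1.10), GATA (1.04) and MEIS (1.03) had smaller ratios. The POU, TCF and LEF, CTCF, NRF1, RFX, REST and NF1 motifs, the ERR site and the direct repeat AGGTCAAAGGTCA were not called. ERR and NRF1 were enriched in replicate 2 alone and in the pooled list, and NF1 in replicate 1 alone. Within 100 bp of the summit only 6 motifs were enriched (FOX, SOX, TEAD, TFAP2, GATA and CAGCTG) and 2 depleted. HNF1 was then in 1 peak window and 4 controls (Fisher exact test, adjusted p = 0.616), and AP-1 was depleted, at 0.890 times the controls (Fisher adjusted p = 0.0165).

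The X chromosome carried few peaks. It had 728, or 4.45 per Mb of sequence, whereas the 19 autosomes ranged from 15.8 (chromosome 3) to 35.6 per Mb (chromosome 11). X held 5.80 protein-coding genes per Mb, within the autosomal range of 5.50 to 14.3. Of its 948 protein-coding genes 323 (34.1%) had a promoter peak, against 45.2% to 63.7% on autosomes. The Y chromosome had 3 peaks. The densities were not tested, since each chromosome gives a single value.

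**Figure D4:**
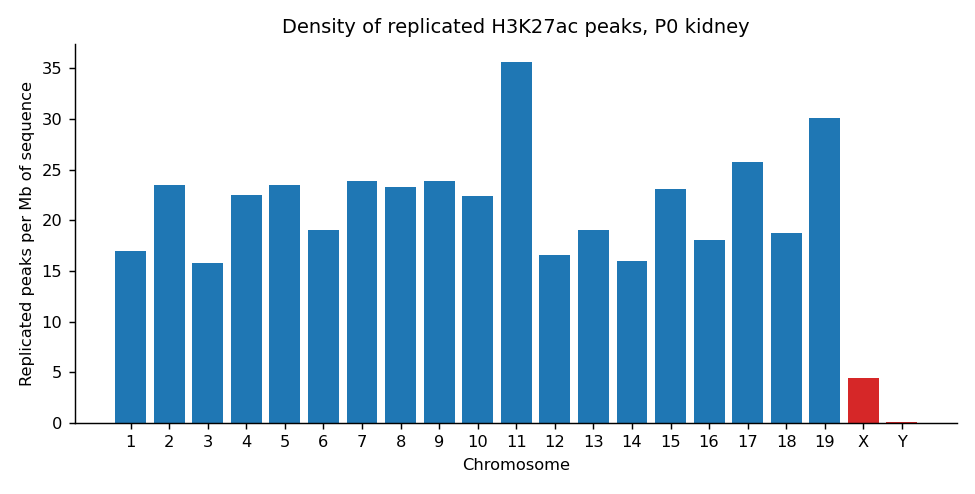
Replicated H3K27ac peaks per Mb of sequenced bases (vertical axis) for each chromosome (horizontal axis), autosomes in blue and the sex chromosomes in red. The autosomes lie between 15.8 and 35.6 peaks per Mb and X at 4.45.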

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

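The tests of gene number on chromosome X and of promoter GC content in podocyte against proximal tubule genes were chosen after the result was seen. The low peak density and promoter share of X were also noticed first and then tested on the same data. Only the GC-matched share and the median enrichment were unseen when those tests were written.

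The pooled list held 46338 peaks (46.9% of it) that the replicated list lacks. The main comparisons leave these out, and only alternatives and the choice of motif controls use them. Of these, 12046 touched a replicate 1 peak only, 19567 a replicate 2 peak only, 590 both and 14135 neither. Their median enrichment was 2.78-fold, against 4.28-fold for the replicated peaks, and their median length 234 bp against 627 bp. In the ranking by score, 88.1% of them lay in the lower 50% of the pooled list. This is what weak peaks near the calling threshold would give, although 63.0% still had q of at most 0.01 and no biological explanation was tested. Separately, 7 replicated peaks lay on unplaced scaffolds and were not analysed further.

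The high promoter share of kidney genes and the low share of genes of other organs were set against promoter GC content. Random lists matched on GC gave 63.7% ± 2.72 (SD) for the kidney class, against 77.4% observed, a difference of 5.02 SD. For the other organs they gave 56.1% ± 3.62 against 14.8%, a difference of -11.4 SD. GC content around the most 5′ start site therefore does not account for the whole of either difference. It raises the random share of the kidney class above the 55.1% of all genes. A promoter peak counted at any start site of a gene, so the GC content of further start sites and their number were not matched. Of the single kidney lists, only stroma (26.5 percentage points) and endothelium (25.4) passed the threshold against GC-matched lists. No list of nephron or collecting duct cells did, so the class value does not show an excess for those cells by themselves. That the shares follow the tissue of origin remains a hypothesis, since other properties of promoters were not matched.

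The low number of peaks on X was set against 3 explanations. For promoters, the values argue against GC content as the whole cause. GC-matched autosomal genes had promoter peaks at 46.8% ± 1.35 (SD) and X at 34.1%, a difference of -9.49 SD. That test used the share of genes with a promoter peak and does not cover X peaks away from promoters. The values argue against gene number, because X had 0.768 peaks per protein-coding gene and the autosomes 1.67 to 3.20. A lower signal from a chromosome with 1 active copy per cell stays open as a hypothesis: X promoter peaks had a median enrichment of 7.62-fold against 9.85-fold on autosomes, -4.46 SD of random autosomal promoters. Enrichment over a control library may cancel part of any difference in DNA copy number, and tissue-restricted gene content of X was not tested.

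Adrenal tissue left on the dissected kidneys was tested by 7 steroidogenic genes, of which 1 had a replicated promoter peak. Between podocyte and proximal tubule genes, the differences from GC-matched lists lay 0.526 SD apart, which promoter GC content allows. Podocyte lay 16.8 percentage points above its GC-matched lists (SD 8.53) and proximal tubule 10.9 above (SD 7.32). With spreads this wide, lists of this size are hardly told apart. The value therefore does not decide whether GC content accounts for the lower promoter share of proximal tubule genes.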

How the results depend on the processing

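The alternatives with genes of 1 list only, with replicated peaks touching both replicates, with random lists not matched and with the domain background as planned were chosen after the result was seen; all other alternatives were planned. No paired analysis was possible because the series has 1 group only. The kidney and other-organ classes kept their difference, and progenitor and proximal tubule genes stayed without a detected one (although its size moved), in each of the 14 values under alternatives. The promoter and intergenic shares of peaks kept their direction and call in each alternative run. Where no cause is given below, the cause was not tested. Depth is unknown, so how many weak peaks each library could show was not assessed, and with 2 pools the spread between animals is unknown.

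The share of replicate 1 and replicate 2 peaks overlapped by the other moved to 59.2% and 45.9% with 50% coverage, and to 78.8% and 54.6% at q of at most 0.01. The intron share relative to random turned to 0.980 by midpoint and 0.998 by any overlap with promoters of 2500 bp, where promoters take intron sequence, and to 0.994 with peaks touching both replicates. The exon share by any overlap turned to 1.07 and 1.11 in single replicates and 1.13 in the pooled list.

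For promoter shares, in percentage points from other genes, random lists not matched took ureteric bud (19.8), loop of Henle (23.0) and distal convoluted tubule (24.8) below the threshold through the form of the test alone, leaving 10 lists above. Random lists matched on GC left 4 lists above. Lists no longer past the threshold were Hox 1 to 8 (21.2), Hox 9 to 11 (26.7), distal convoluted tubule (19.2), immediate early (16.0), signalling (7.90), loop of Henle (20.96), podocyte (16.8), renal vesicle (8.83) and ureteric bud (8.27), while Hox 12 and 13 passed it (-61.0). With the most 5′ start site, distal convoluted tubule (8.74) and ureteric bud (16.6) missed it and proximal tubule turned (-1.27). With promoters of 2500 bp, distal convoluted tubule (23.4) and ureteric bud (18.4) missed it. In the pooled list adrenal (-24.2) and distal convoluted tubule (20.8) missed it and progenitors passed (22.7). With peaks touching both replicates, distal convoluted tubule (21.7) and loop of Henle (11.9) missed it and Hox 12 and 13 passed (-53.3). With genes of 1 list only, which leaves fewer genes, loop of Henle (22.7) and renal vesicle (28.3) missed it. In single replicates (lowest and highest), progenitors passed it in both (26.3 and 28.2), distal convoluted tubule missed it in replicate 1 (19.5 and 26.9), loop of Henle missed it in replicate 2 (20.1 and 27.1), and Hox 12 and 13 passed it in replicate 1 (-55.6 and -41.5).

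For acetylated length (log2, list minus random), the number of peaks in place of bp took cell cycle (0.27), oxidative phosphorylation (0.37) and hepatocyte (-0.36) below the threshold and progenitors (0.70) and renal endocrine genes (0.60) past it. With peaks touching both replicates, Hox 12 and 13 (-4.45), adrenal (-2.85), gonad (-3.05) and progenitors (2.44) passed, giving 8 lists below. Others past it were Hox 12 and 13 (-5.06), loop of Henle (3.15) and progenitors (2.97) in the pooled list, gonad at q of at most 0.01 (-3.22), and gonad (-2.77), loop of Henle (2.25) and progenitors (2.76) with a reach of 25000 bp. In single replicates (lowest and highest), progenitors (2.54 and 3.37) and loop of Henle (2.36 and 3.06) passed in both. In replicate 2 Hox 12 and 13 (-4.91 and -3.57) and gonad (-2.78 and -1.66) passed, and in replicate 1 distal convoluted tubule (2.33 and 2.67) and hepatocyte (-2.73 and -1.97) missed it. Lists not called in either still moved: intercalated (0.13 and 1.12), renal endocrine (0.49 and 1.66), lung (0.34 and 0.65), erythroid (-1.85 and -0.42), macrophage (-1.19 and -0.31) and adrenal (-2.02 and -1.33). The bp given for single genes are those of the replicated list unless a replicate is named, and they too depended on the list. In replicate 1 alone 135 such values were marked as moved and 86 as the same, and in replicate 2 alone 67 and 154.

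With the domain background as planned the same 3 lists were above, and Hox groups 1 to 8 came to 3 of 21 in place of 4 of 22. Domain lists above numbered 6 with stitching at 5000 bp, 5 in the pooled list, 4 with 250 domains and 1 with peaks touching both replicates. They numbered 6 in replicate 1 alone and 4 in replicate 2 alone. Hox groups 1 to 8 were among the lists above in each single replicate, in the pooled list and with 250 domains. Podocyte genes were in replicate 1 alone, and immediate early genes in replicate 1 alone and in the pooled list. In replicates 1 and 2 alone, muscle lay at 14.8 and -3.41 and distal convoluted tubule at -3.44 and 2.48 percentage points. In percentage points, lung turned to 5.26 with peaks touching both replicates and 4.84 at 5000 bp, proximal tubule to 3.41 at 5000 bp, muscle to 5.75 in the pooled list and intercalated cells to -3.70 at q of at most 0.01. With 250 domains, distal convoluted tubule turned to -1.88, intercalated cells to -1.88 and ureteric bud to -1.88, none of them having a member there. Windows of 100 bp left 6 motifs enriched and 2 depleted and turned AP-1 to 0.890, CTCF to 0.377, HNF1 to 0.250, NF1 to 0.625 and RFX to 0.5 (ratio to controls). HNF4, GRHL, ETS, MEF2, the Six2 site and MEIS were not called there, HNF4 (1.18) and GRHL (1.40) not with controls at 20000 bp, MEIS (1.02) not with peaks touching both replicates and GRHL (1.16) not in replicate 2 alone. ERR (1.2 in replicate 2 alone, 1.11 pooled), NRF1 (1.79, 1.83 and 2.46 with controls at 20000 bp), NF1 (1.78 in replicate 1 alone, 2.21 with controls at 20000 bp) and TCF and LEF (1.06 pooled) were called there only. No ratio could be given at 100 bp for REST, which had no control match. Controls at 20000 bp turned CTCF to 0.976 and RFX to 0.778, the pooled list turned RFX to 0.813 and q of at most 0.01 turned it to 0.571. At q of at most 0.01 and in the pooled list the HNF1 ratio was 4.86 and 5. In replicates 1 and 2 alone it was 3.59 and 4.00, CTCF lay at 0.900 and 1.02 and RFX at 1.07 and 0.714.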

Other observations

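The comparisons in this part were not among the planned ones and were chosen after the peak lists had been seen. Acetylation at genes that do not encode proteins was rarer. Of 5854 lincRNA genes, 920 (15.7%) had a replicated peak within 1000 bp of the most 5′ start site, against 51.3% of protein-coding genes by that start site alone. The share was 32.5% of 2959 antisense genes, 14.4% of 2202 microRNA genes and 9.22% of 1507 snoRNA genes, and 1.79% of 9940 processed pseudogenes. Among genes over 5000 bp from any coding start site it was 11.4% for lincRNA, 13.7% for antisense, 5.53% for microRNA and 3.65% for snoRNA genes. These shares were not tested.

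Promoter calls were mostly shared by the replicates: 11869 protein-coding genes had a peak in both, 321 in replicate 1 only and 889 in replicate 2 only. Of the genes called in both, 119 had no peak of the replicated list at the promoter. Among the 622 listed genes these were 4: Cubn, a receptor of the proximal tubule, Esrrb, Nphs1, which encodes nephrin, and Six1. Nphs1 had 293 bp of assigned peaks in replicate 1 and 196 bp in replicate 2, and Six1 had 456 and 255 bp. The absence of a replicated promoter peak at Nphs1 in the podocyte list is thus an absence from the replicated list, since each replicate list touches its promoter. Whether the peaks of the replicates overlap was not checked. The shortest peak of each replicate list had 190 bp, so the lengths at Nphs1 are small.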
